A study of Arabidopsis thaliana with 8 samples.

How the data were processed

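RNA came from stems 10 cm long of Arabidopsis thaliana (accession Col-0) grown in soil at 23 °C with 16 h of light and 8 h of dark, per the labels' protocols. Per the same labels, 200 ng of total RNA was labelled with Cy3 by Agilent's Low Input Quick Amp kit and hybridised to 44k Agilent arrays in a single colour. The 8 arrays formed 2 groups of 4 by their labels, the nst1 nst3 double mutant and the same mutant with the construct. Per the file headers, the deposited intensity values were extracted with Agilent Feature Extraction version 11.5.1.1 on a grid of build TAIR10; the submitters' processing notes name Agilent Feature Extraction 9.1.3.1, and the discrepancy stays open. The deposited processed signal is an intensity, corrected for background by that program, on a linear scale. The authors' value table holds natural log values. Set against the scanner files, each of its columns was the natural log of the processed signal minus a constant, 7.39 for every control array and 7.15 for every transgenic array, to within 0.0002 log units. The array's own brightness was therefore not removed within a group, and how the authors chose the constants is not given in the sources used here. The column medians of the value table ran from -1.26 to -1.05 in the controls and from -1.23 to -0.84 in the transgenic arrays. That table served as an alternative.

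The main values were log2 of the processed signal divided by the array's 75th percentile over the 43603 non-control probes, with a floor at 0.01 of it (-6.64 on the log2 scale) set after scaling. Control spots and spots marked as outliers were left out and spots of a probe were averaged; a probe whose spots were all marked kept its value. A probe entered the tests if it was well above background on at least 4 of the 8 arrays. Probes were named by their RefSeq accession, without versions, through a gene table of assembly TAIR10.1; 34348 probes matched 25410 loci, and 9255 probes had no match and entered 1 alternative only. No coordinates are given, since the array's build and that of the gene table are named differently. Of several probes of a gene the brightest stood for it, which left 19609 genes; 6006 of them had more than 1 usable probe, and for 19 of these the probes passed in opposite directions. Probes of near-identical genes can bind each other's transcripts.

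Groups were compared gene by gene with limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3) without covariates, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. Standard errors are those of the moderated fit. Gene lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01, and p-values were adjusted over the 26 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance to one side, were alternatives. The targeted genes were also tested with an exact two-sided permutation test. The lists, the tests, most alternatives and the rule for naming genes were set before the data were examined. The rule took the targeted genes, the 8 largest rises and the 8 largest falls whose groups did not overlap and that were above background on at least 1 array of each group, up to 4 passing members of each wall list and 2 of each other list by size of change, and up to 3 genes in each direction that were not above background in one group. The expansin-like genes and CESA5 were named after their values were seen. A gene below background on every array of a group has only a bound, and 1 locus carrying several names is given by the symbol of the list or gene table.

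The alternatives were normexp background correction of the median signals with an offset of 50 (the mean signals that had been planned were not among the columns), scaling by the median, quantile normalization, the authors' value table, other filters on dim probes, a floor of 0.001, the mean of a gene's probes, every probe on its own, eBayes with trend and robust settings, array weights, the replicate number as a block, other thresholds and leaving out each array. After seeing the data, scaling on the E1A spike-in probes and leaving out control arrays 2 and 3 together were added. The 75th percentile of the processed signal was 3632, 2774, 3330 and 3642 on control arrays 1 to 4 and 3255, 2344, 2615 and 2423 on transgenic arrays 1 to 4. A simulation of 19609 genes used the observed spread of each gene and 200 changed genes. The fit recovered 19.0% of changes of 0.5 log2 units, 62.0% of changes of 1 and 85.9% of changes of 2. It called 6 of 19398 unchanged genes. The list test called a shifted list of 11 genes and none of the others. The simulated genes varied independently of each other, so the simulation does not test list calls on correlated genes. It also changed far fewer genes than the 10634 called in the data, so these recovery rates may not carry over.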

Results

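Gene expression was measured in stems of Arabidopsis thaliana that were 10 cm long, on 8 single-colour Agilent arrays of the whole transcriptome. The 4 control arrays came from the nst1-1 nst3-1 double mutant, called nst1 nst3 here. It lacks working copies of NST1 and NST3, the NAC transcription factors that switch on secondary wall formation in fibers. The other 4 arrays came from the same double mutant carrying the construct NST3pro:CEF2-VP16:HSP, called CEF2-VP16 nst1 nst3 or transgenic here. In that construct the promoter of NST3, which is active in fibers, drives an AP2/ERF transcription factor joined to VP16, a viral activation domain. The sample labels name the factor CEF2 and the series' design text names it ERF035. According to the series title the study asked how AP2/ERF factors give fibers of nst1 nst3 thickened primary walls, and the single comparison is transgenic stems against nst1 nst3 stems. The 75th percentile of the processed signal lay between 2344 and 3642 units, and between 30289 and 32382 of 43603 probes were well above background on an array. No label says that the 4 arrays of a group came from separate plants, so p-values measure only the spread between these samples, which may be technical. The number of arrays, 4 per group, limits the precision.

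The 4 control arrays lay on 1 slide and the 4 transgenic arrays on another, so that slide and genotype cannot be told apart. The transgenic arrays correlated with each other at r = 0.987 to 0.994 over 19609 genes, the control arrays at 0.953 to 0.987, and arrays of different groups at 0.877 to 0.936. The median standard deviation of a gene was 0.21 log2 units in the control group and 0.13 in the transgenic group.

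ERF035 (AT3G60490) was 7.72 ± 0.68 log2 units (SE, n = 4 per group) higher in the transgenic stems, a 210-fold difference. It read 4.14 ± 0.11 (SD, n = 4) on the log2 scale of signal over the array's 75th percentile in the transgenic stems and -3.58 ± 1.56 in the controls, where the 4 arrays read -3.07, -2.38, -5.87 and -2.99. Control array 3 was the lowest, and without it the difference was 6.95. NST3 (AT1G32770), one of the mutated genes, read 0.71 ± 0.41 in the controls and 0.19 ± 0.27 in the transgenic stems. NST1 (AT2G46770) read -3.07 ± 0.35 and -3.60 ± 0.42. Neither difference passed the test, with limma adjusted p = 0.076 for NST3 and 0.102 for NST1. NST3 passed without control array 1 (-0.70) and NST1 without transgenic array 2 (-0.71), and both passed when the arrays were scaled on spike-in probes (-0.96 for NST3 and -0.97 for NST1). Where the NST1 and NST3 probes lie relative to the mutations is not given in the sources used here, so these probes do not check the genotype. NST2 (AT3G61910), their relative with a role in anther walls, fell by 2.67 ± 0.49 (SE; limma adjusted p = 0.00251). An exact two-sided permutation test over the 70 assignments of the 8 arrays gave p = 0.0286 for ERF035 and for NST2, the smallest it can give, 0.0857 for NST3 and 0.143 for NST1.

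**Figure D1:**
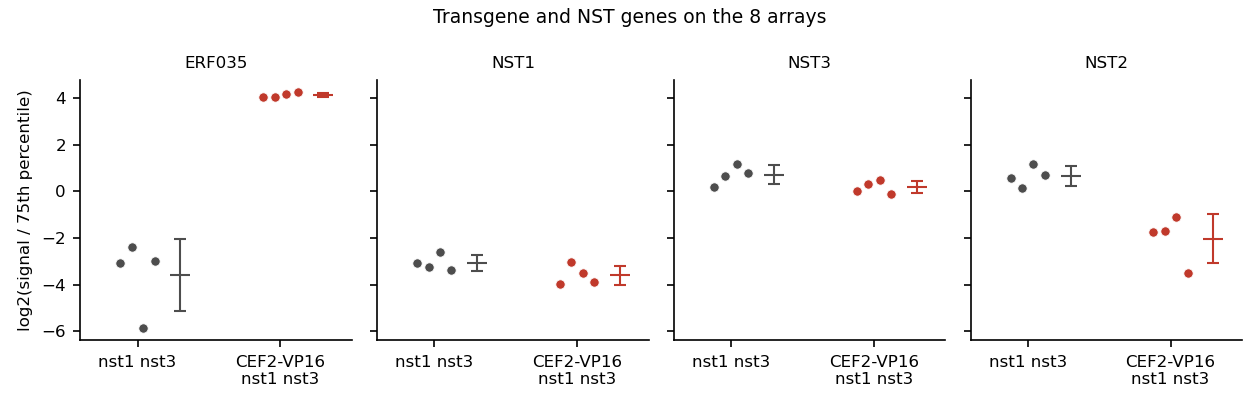
Log2 of signal over the 75th percentile of the array (y axis) for ERF035 and the NST genes on the 4 nst1 nst3 arrays (grey) and the 4 CEF2-VP16 nst1 nst3 arrays (red); points are arrays, dashes with bars are mean ± SD. ERF035 read between 4.05 and 4.27 on the transgenic arrays and at most -2.38 on the control arrays.

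Much of the measured transcriptome differed between the genotypes. Of 19609 genes, 5776 were higher and 4858 lower in the transgenic stems (limma, Benjamini-Hochberg adjusted p under 0.05), and 2101 of the higher and 2061 of the lower ones differed at least 2-fold. The 2 groups did not overlap for 50.7% of the genes, against 2.86% by chance. Agilent's E1A spike-in probes, which read control RNA added before labelling, were 0.38 to 0.50 log2 units higher on the transgenic arrays for the 8 of 10 that were detected. Scaling on them instead of the 75th percentile moved the median gene by -0.43 log2 units and gave 2104 higher and 7843 lower genes, 21.2% higher against 54.3%. All changes below are relative to the 75th percentile of the array, and list counts with spike-in scaling are given where they differ.

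The largest rises, next to that of ERF035, were 8.17 ± 1.36 for GER3 (AT5G20630, a germin-like protein), 7.44 ± 1.07 for LP1 (AT2G38540, a lipid transfer protein), 7.35 ± 0.11 for AT1G62333, 7.33 ± 1.67 for AT2G10940, 6.56 ± 1.02 for ADS4 (AT1G06350, a fatty acid desaturase-like protein), 6.38 ± 1.15 for DGR2 (AT5G25460) and 6.28 ± 0.76 for XTH8 (AT1G11545), all in log2 units with SE and n = 4 per group. GER3, LP1 and XTH8 were well above background on 3 of the 4 control arrays and AT1G62333 on 1 of 4. Values lay at the floor of the scale on 2 control arrays for GER3, LP1 and XTH8, on 3 for AT1G62333 and on 1 for ADS4. That understates the rises of these genes, and for AT1G62333 it also makes the SE small. AT2G10940 and DGR2 had no control value at the floor. Control array 2 read nearest to the transgenic arrays, and without it GER3 rose by 9.49, LP1 by 8.39, AT2G10940 by 8.80, ADS4 by 7.67, DGR2 by 7.63 and XTH8 by 7.07. AT2G10940 rose by 6.40 without control array 1, 6.13 without control array 3 and 8.01 without control array 4; GER3 rose by 7.33 without control array 1 or 3, and DGR2 by 5.67 without control array 3.

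The largest falls were those of 8 genes. RRTF1 (AT4G34410, an ERF transcription factor of redox responses) read -9.35 ± 1.5, JAZ7 (AT2G34600, a jasmonate signalling repressor) -8.10 ± 1.49, CYP94B3 (AT3G48520, which breaks down jasmonoyl-isoleucine) -7.65 ± 0.83, AT4G27654 -7.57 ± 1.12, DDF1 (AT1G12610, a CBF-like factor) -7.48 ± 0.98, GRX480 (AT1G28480, a glutaredoxin) -7.38 ± 1.24, WRKY40 (AT1G80840) -7.37 ± 1.16 and LOX4 (AT1G72520, a lipoxygenase) -7.33 ± 0.99. JAZ7, GRX480 and DDF1 were well above background on 2 of the 4 transgenic arrays, and RRTF1 and CYP94B3 on 3. JAZ7 and GRX480 were at the floor of the scale on 3 transgenic arrays and DDF1, RRTF1 and CYP94B3 on 1, which understates their falls. Control array 3 had the lowest levels of most of these genes among the controls. Without it RRTF1 read -10.97, JAZ7 -9.77, CYP94B3 -8.47, AT4G27654 -8.63, DDF1 -8.34, GRX480 -8.73, WRKY40 -8.59 and LOX4 -8.43. Without control array 1 RRTF1 read -8.62, JAZ7 -7.23, CYP94B3 -6.96 and DDF1 -6.71, and without transgenic array 2 AT4G27654 read -8.25.

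A further 81 genes were above background on all transgenic arrays and on no control array, and 104 genes showed the opposite. Bounds for them set the mean of the bright group against the higher of the lowest signal among probes well above background and the dim probe's own signal. That lowest signal lay at or near the floor of the scale, so the bounds stay close to the fitted changes. They allow little for signal too dim to read and nothing for the spread between arrays, and are not strict lower limits. The bound was 29.2-fold higher in the transgenic stems for AT1G62770, 15.9-fold for AT1G49390 and 14.9-fold for AT4G34770 (limma adjusted p = 2.51e-05, 3.01e-05 and 3.55e-05). These equal the fitted changes of 4.87, 3.99 and 3.90 log2 units, which fell to 4.64, 3.86 and 3.69 in the lowest fit without 1 array. Most of their control values lay at the floor, which narrows the spread behind these p-values. In the other direction the bound was 63.9-fold lower for AT1G70390 and 50.7-fold for AGC2-1 (AT3G25250, a protein kinase also known as OXI1). For GAMT2 (AT5G56300, a gibberellin methyltransferase) it was 45.1-fold (limma adjusted p = 0.00207, 0.000198 and 2.46e-05 for the 3 genes in this order). Without control array 3 the fitted changes of AT1G70390 and AGC2-1 were -7.30 and -6.35, against -6.07 and -5.74.

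Of 26 gene lists fixed beforehand, 14 stood higher and 3 lower than other genes in limma's camera test with a preset correlation of 0.01 between genes. None of the 17 passed when camera estimated the correlation from the 8 arrays. For each of these 17 the adjusted p with that estimated correlation is given beside the preset one. In 20 lists the counts of rising and falling members were the same when adjusted over the list alone; the other 6 are given both ways. Over the 11 wall lists together, 125 of 198 measured genes rose and 23 fell, or 84 and 43 with spike-in scaling.

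Genes of primary wall cellulose synthesis rose nearly as a block. Of 14 measured members 13 rose and none fell, with a median of 0.96 log2 units (camera adjusted p = 5.99e-06; adjusted p = 0.570 with an estimated correlation). The largest rises were in genes of the cellulose synthase complex's companions, with 1.98 ± 0.12 for CC2 (AT5G42860) and 1.15 ± 0.08 for CC1 (AT1G45688), which tie the complex to microtubules, 1.39 ± 0.12 for COB (AT5G60920), a surface protein that orients cellulose, and 1.27 ± 0.12 for STL1 (AT2G41770), which acts in assembly of the complex (SE, n = 4 per group). CESA5 read 0.43 and did not pass. With spike-in scaling 9 of the 14 rose.

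Pectin genes moved in the same direction, with a larger median change among those that modify pectin than among those that make it. Of 20 measured modification genes 15 rose and 2 fell, with a median change of 4.01-fold (camera adjusted p = 0.000566; adjusted p = 0.570 with an estimated correlation). With spike-in scaling 14 rose and 2 fell, and with no filter on dim probes the median was 1.19 log2 units. Pectate lyase-like genes led the list, with 6.23 ± 1.2 for AT5G63180, 4.35 ± 0.37 for AT3G07010 and a 28.0-fold rise of AT5G48900, and the pectin methylesterase gene PME5 (AT5G47500), above background on 1 of the 4 control arrays, rose by 4.22 ± 0.33. AT5G63180 rose by 7.32 without control array 2, 5.54 without control array 1 and 5.40 without control array 3. Of 25 pectin synthesis genes 16 rose and 5 fell, with a median of 0.49 (adjusted p = 0.0101; adjusted p = 0.570 with an estimated correlation; 0.0509 without control array 3). Among them were CGR3 (AT5G65810, pectin methylation) at 2.11 ± 0.18, RRT1 (AT5G15740, rhamnogalacturonan synthesis) at 1.95 ± 0.15, GALS1 (AT2G33570, galactan synthesis) at 1.90 ± 0.30 and GAE6 (AT3G23820, galacturonate supply) at 1.28 ± 0.11. With spike-in scaling 8 pectin synthesis genes rose and 7 fell. The difference between the 2 lists was not tested.

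Of 18 measured expansins 12 rose and 3 fell, or 12 and 4 adjusted over the list alone, with a median of 2.37 (camera adjusted p = 0.0101; adjusted p = 0.570 with an estimated correlation). EXPA8 (AT2G40610) rose by 5.96 ± 0.91, EXPA11 (AT1G20190) by 5.21 ± 0.58, EXPA5 (AT3G29030) by 4.91 ± 0.63 and EXPB1 (AT2G20750), above background on 3 of the 4 control arrays, by 4.51 ± 0.79. Without control array 2 these rises were 6.86, 5.84, 5.57 and 5.34, and EXPA8 rose by 5.34 without control array 3. The 3 that fell were the expansin-like genes EXLA1, EXLA3 and EXLB1, at -2.63, -3.34 and -1.05; with spike-in scaling 12 expansins rose and 4 fell. With no filter on dim probes the expansin median was 0.50. Of 24 xyloglucan endotransglucosylases, the enzymes that cut and rejoin xyloglucan, 12 rose and 3 fell (13 and 3 adjusted over the list alone), with a median of 1.49, but the list did not pass (adjusted p = 0.0531). It passed without control array 2 (median 2.18; 0.00583), control array 1 (0.0402) or transgenic array 3 (0.0458), and with spike-in scaling, where 11 rose and 6 fell. XTH8, XTH31 (AT3G44990) and XTH4 (AT2G06850) rose by 6.28 ± 0.76, 6.09 ± 0.15 and 5.11 ± 0.85, while the touch gene XTH22 (AT5G57560, also TCH4) read -3.97 ± 0.56. Without control array 2 XTH8 rose by 7.07 and XTH4 by 6.04.

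Of 18 xyloglucan synthesis and trimming genes 9 rose and 3 fell (10 and 4 adjusted over the list alone), with a median of 0.56 (camera adjusted p = 0.0432; adjusted p = 0.602 with an estimated correlation). That call was lost without control array 3 (0.139), control array 4 (0.0572) or transgenic array 1 (0.0572). With spike-in scaling 6 rose and 5 fell, with a median of 0.12. BGAL10 (AT5G63810) and XYL1 (AT1G68560), which trim xyloglucan side chains, rose by 3.22 ± 0.29 and 2.30 ± 0.22, and the xylosyltransferase gene XXT3 (AT5G07720) rose by 1.90 ± 0.27 while XXT1 (AT3G62720) read -2.65 ± 0.51. Of 14 arabinogalactan protein genes 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 1.72 (adjusted p = 0.000786; adjusted p = 0.570 with an estimated correlation). With spike-in scaling 11 rose and 1 fell. FLA1 (AT5G55730), FLA2 (AT4G12730) and FLA9 (AT1G03870) rose by 4.28 ± 0.37, 3.14 ± 0.53 and 2.95 ± 0.37, and AGP10 (AT4G09030) read -2.84 ± 0.59, or -3.44 without control array 3.

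**Figure D2:**
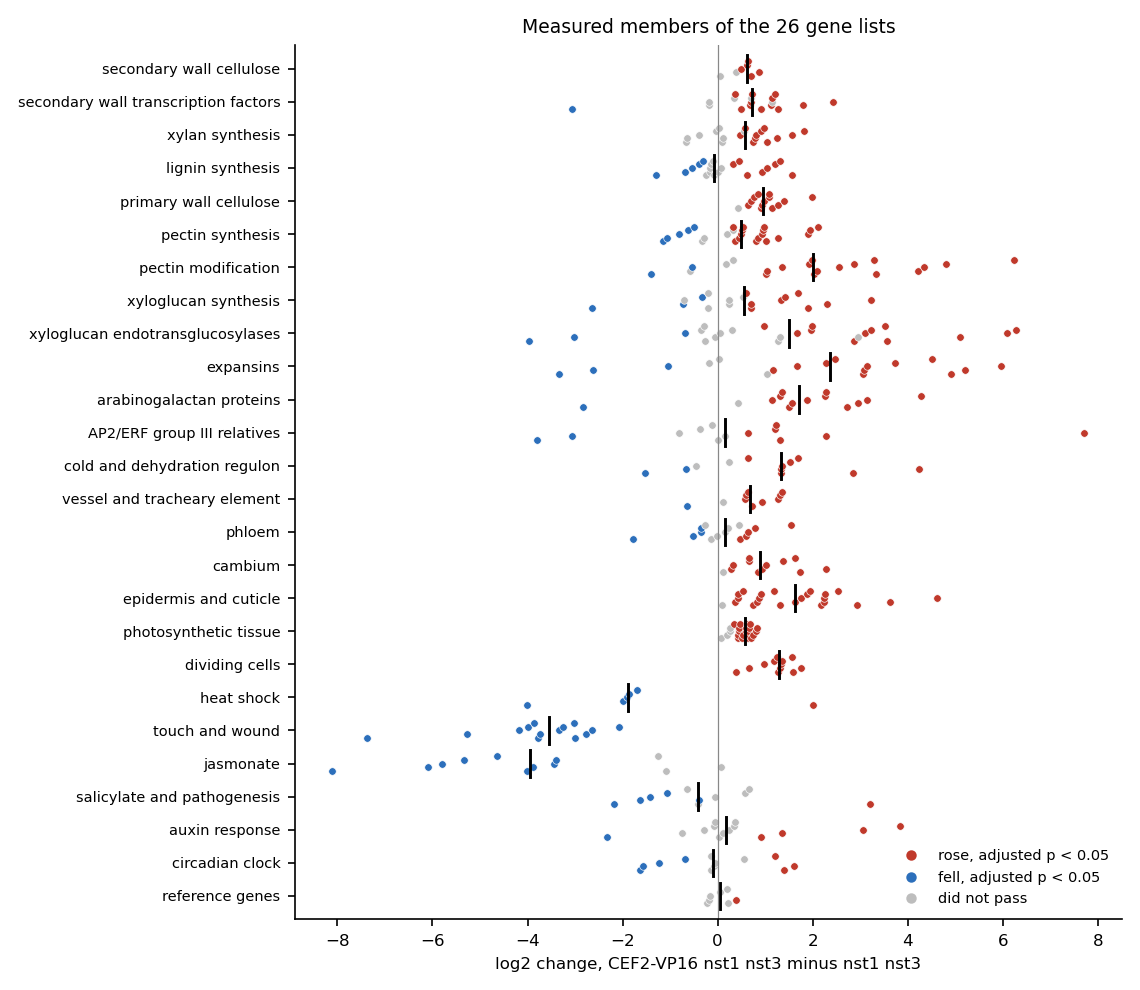
Log2 change, CEF2-VP16 nst1 nst3 minus nst1 nst3 (x axis), of each measured member of the 26 gene lists (y axis); red points rose and blue points fell at limma adjusted p under 0.05, grey points did not pass, and black bars are list medians. All 14 touch and wound genes lie left of 0, with a median of -3.55, and all 14 primary wall cellulose genes lie right of it.

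The lists of secondary wall formation had medians under 1 log2 unit, as had those of primary wall cellulose, pectin synthesis and xyloglucan synthesis. Of 7 secondary wall cellulose genes 5 rose and none fell, with a median of 0.62, and the list did not pass (camera adjusted p = 0.0598), though it did without control array 1 (0.0483), control array 2 (0.0204) or transgenic array 2 (0.0481). CESA8 (AT4G18780) and CESA4 (AT5G44030), subunits of the secondary wall cellulose synthase, rose by 0.86 ± 0.15 and 0.65 ± 0.17, CTL2 (AT3G16920) by 0.70 ± 0.20 and COBL4 (AT5G15630) by 0.62 ± 0.16 (SE, n = 4 per group). CTL2 missed the threshold without transgenic array 3 (0.0514). With spike-in scaling none of the 7 rose or fell, and CESA8, CESA4, CTL2 and COBL4 read 0.42, 0.20, 0.26 and 0.18. Of 18 secondary wall transcription factors 12 rose and 1 fell (12 and 2 adjusted over the list alone), with a median of 0.72 (adjusted p = 0.0125; adjusted p = 0.570 with an estimated correlation). The lignin regulators MYB58 (AT1G16490) and MYB63 (AT1G79180) rose by 2.44 ± 0.28 and 1.80 ± 0.26 and MYB54 (AT1G73410) by 1.27 ± 0.14. MYB69 (AT4G33450) read -3.07 ± 0.46 and was above background on 2 of the 4 transgenic arrays. With spike-in scaling 5 of the 18 rose and 3 fell.

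Of 19 xylan synthesis genes 11 rose and none fell, with a median of 0.59 (camera adjusted p = 0.0335; adjusted p = 0.631 with an estimated correlation; 0.0894 without control array 3 and 0.0562 without control array 4). F8H (AT5G22940), GXM2 (AT4G09990), ESK1 (AT3G55990) and IRX15L (AT5G67210) rose by 1.81 ± 0.28, 1.57 ± 0.38, 1.26 ± 0.19 and 1.03 ± 0.37. IRX15L had an adjusted p of 0.0467 and missed the threshold in 6 of the 8 fits that left out 1 array. With spike-in scaling 3 of the 19 rose and 5 fell, and IRX15L read 0.59 and did not pass. Lignin synthesis genes went both ways, 8 of 21 rising and 5 falling, with a median of -0.08, a mean of 0.16 and no call (adjusted p = 0.824). With spike-in scaling 5 rose and 10 fell, with a median of -0.52. F5H1 (AT4G36220), CYP98A3 (AT2G40890) and the laccase gene LAC17 (AT5G60020) rose 2.97-fold, 2.47-fold and 2.29-fold, while PAL2 (AT3G53260), at the entry of the pathway, was 2.46-fold lower.

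Among 13 listed members of ERF035's AP2/ERF group, the transgene's own gene included, 6 rose and 2 fell, with a median of 0.14 (camera adjusted p = 0.328). The list, fixed beforehand, does not hold the CBF-like gene DDF1, given above among the largest falls. CBF2 (AT4G25470), a regulator of the cold response, read -3.79 ± 0.80, or -4.40 without transgenic array 2. Of 12 cold and dehydration genes 8 rose and 2 fell, with a median of 1.34 (adjusted p = 0.0335; adjusted p = 0.570 with an estimated correlation; 0.0894 without control array 3). RD29A (AT5G52310) rose by 4.23 ± 0.35 and COR15A (AT2G42540) by 2.85 ± 0.54. With spike-in scaling 5 AP2/ERF relatives rose and 2 fell, with a median of -0.30, and 7 cold and dehydration genes rose and 3 fell.

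Markers of several stem tissues were higher in the transgenic stems. Of 23 epidermis and cuticle genes 22 rose and none fell, with a median of 1.63 (camera adjusted p = 5.39e-06; adjusted p = 0.570 with an estimated correlation). CYP86A4 (AT1G01600, cutin synthesis) rose by 4.62 ± 0.80, or 5.48 without control array 2, and WSD1 (AT5G37300, wax ester synthesis) by 3.63 ± 0.65. All 12 genes of dividing cells rose, with a median of 1.29 (adjusted p = 7.77e-05; adjusted p = 0.570 with an estimated correlation), among them KNOLLE (AT1G08560, the syntaxin of the cell plate) at 1.76 ± 0.19 and CYCA1-1 (AT1G44110) at 1.58 ± 0.13. Of 12 cambium genes 11 rose and none fell, with a median of 0.89 (adjusted p = 0.000786; adjusted p = 0.456 with an estimated correlation). WOX4 (AT1G46480), which keeps the cambium dividing, and ANT (AT4G37750) rose by 2.28 ± 0.39 and 1.74 ± 0.17. With spike-in scaling 13 epidermis genes, 8 genes of dividing cells and 5 cambium genes rose and none fell.

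Of 24 photosynthetic genes 20 rose and none fell, with a median of 0.56 (camera adjusted p = 0.000241; adjusted p = 0.570 with an estimated correlation). LHCB2.1 (AT2G05100) and PSAD1 (AT4G02770) both rose by 0.82, with SE 0.14 and 0.13. Quantile normalization left 12 of the 24 higher, with a median of 0.22, and spike-in scaling 1, with LHCB2.1 at 0.38 and not passing. Of 10 vessel genes 8 rose and 1 fell, with a median of 0.68 (adjusted p = 0.0466; adjusted p = 0.602 with an estimated correlation). That call was lost without control array 3 (0.0795), control array 4 (0.0564), transgenic array 1 (0.0587) or transgenic array 4 (0.0572). VND1 (AT2G18060), a NAC regulator of vessels, and the protease gene XCP1 (AT4G35350) rose by 1.35 ± 0.23 and 1.32 ± 0.31, and with spike-in scaling 3 vessel genes rose and 1 fell. Phloem genes went both ways, 5 of 15 rising and 4 falling (median 0.16; adjusted p = 0.824; 1 rising and 6 falling with a median of -0.28 with spike-in scaling), with OPS (AT3G09070) 2.92-fold higher and the sucrose exporter gene SWEET11 (AT3G48740) at -1.79 ± 0.35.

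Genes induced by touch and wounding were lower in the transgenic stems without exception. All 14 measured members fell, with a median of -3.55 log2 units (camera adjusted p = 2.12e-06; adjusted p = 0.570 with an estimated correlation). WRKY40 and the calmodulin-like gene CML38 (AT1G76650) read -7.37 ± 1.16 and -5.26 ± 0.74, and WRKY40 -8.59 without control array 3. Of 12 jasmonate genes 9 fell and none rose, with a median of -3.95 (adjusted p = 0.00180; adjusted p = 0.570 with an estimated correlation). The median was -4.79 without control array 3, and 11 fell with spike-in scaling. JAZ7 and JAZ5 (AT1G17380) read -8.10 ± 1.49 and -6.10 ± 0.81, or -9.77 and -7.00 without control array 3; without control array 1 JAZ7 read -7.23. The control arrays differed widely here. The mean of the jasmonate list was 2.80, 3.13, -1.36 and 1.70 on control arrays 1 to 4, and between -2.74 and -1.79 on the transgenic arrays.

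Heat shock genes were lower with 1 exception. Of 6 measured members 5 fell and 1 rose, with a median of -1.89 (camera adjusted p = 0.0101; adjusted p = 0.456 with an estimated correlation). With no filter on dim probes the median was -0.14. The regulator HSFA2 (AT2G26150) read -4.00 ± 0.42, while HSP18.2 (AT5G59720) rose by 2.01 ± 0.42. The genotype label of the transgenic plants ends the construct with HSP, which the labels do not spell out. Whether the HSP18.2 probe also reads the transcript of the construct was not tested, so its rise may not be that of the plant's own gene. Of 11 salicylate and pathogenesis genes 1 rose and 5 fell, with a median of -0.40 and no call (adjusted p = 0.126); with spike-in scaling 1 rose and 6 fell. NIMIN1 (AT1G02450) rose by 3.20 ± 0.40, and PAD4 (AT3G52430), a component of immune signalling, read -2.17 ± 0.22.

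Of the auxin response genes 4 of 14 rose and 1 fell, and camera did not separate the list from other genes (median 0.17; camera adjusted p = 0.335; fry adjusted p = 0.0156; 3 rising and 2 falling with a median of -0.27 with spike-in scaling). SAUR15 (AT4G38850) and SAUR9 (AT4G36110) rose by 3.83 ± 0.91 and 3.06 ± 0.15, above background on 3 and on 1 of the 4 control arrays, and SAUR15 rose by 4.79 without control array 2. Of 12 circadian clock genes 3 rose and 4 fell, with a median of -0.10 (adjusted p = 0.599); with spike-in scaling 3 rose and 5 fell. The evening gene LUX (AT3G46640) rose by 1.60 ± 0.23, and RVE8 (AT3G09600), which peaks in the morning, read -1.63 ± 0.17. Of 7 reference genes 1 rose and none fell, with a median of 0.05 (adjusted p = 0.986), and none passed adjusted over the list alone. With spike-in scaling none rose and 3 fell, with a median of -0.39, and with normexp background correction 1 rose and 2 fell, with a median of -0.11. EF1A (AT5G60390) rose by 0.38 ± 0.12, and 2 of its 5 probes changed in the other direction. Its value was -0.07 with spike-in scaling, and it missed the threshold in 5 of the 8 fits that left out 1 array.

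**Figure D3:**
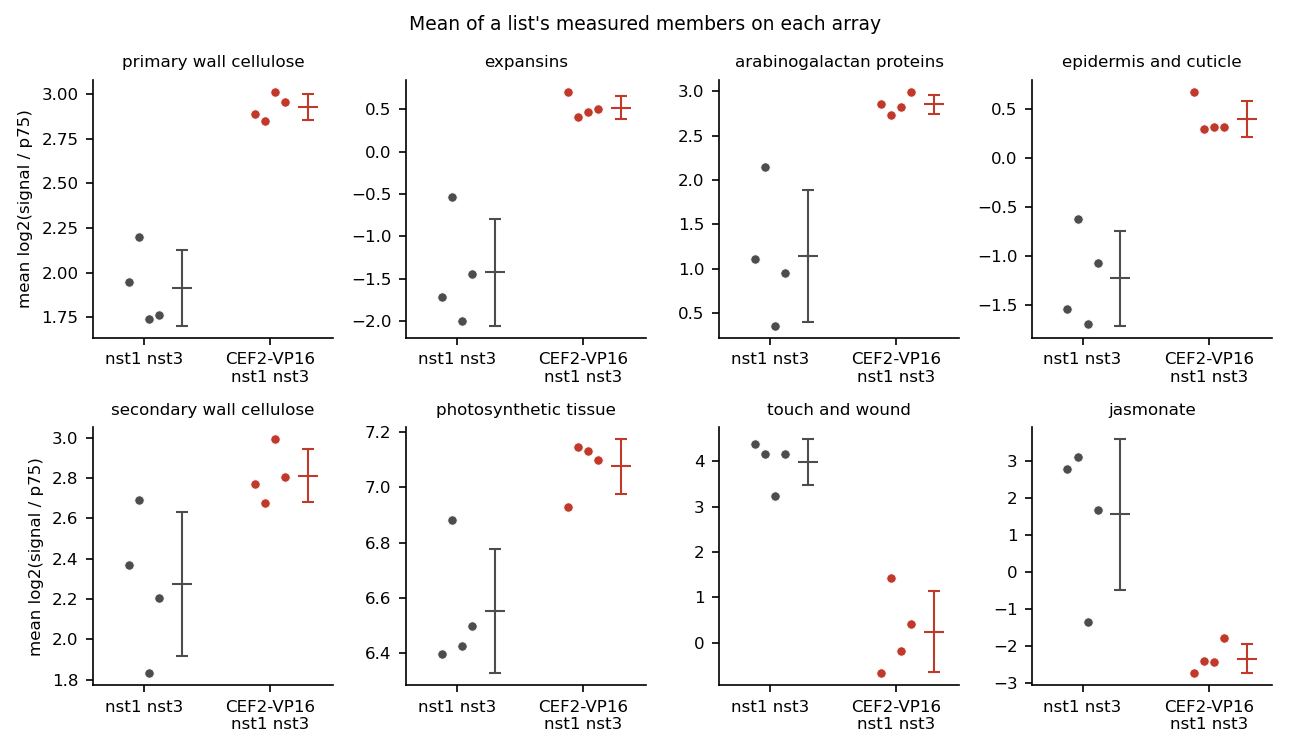
Mean log2 of signal over the 75th percentile (y axis, scale differing between panels) of the measured members of 8 gene lists on each nst1 nst3 array (grey) and each CEF2-VP16 nst1 nst3 array (red); points are arrays, dashes with bars are mean ± SD, n = 4. The expansin mean was 0.40 to 0.71 on the transgenic arrays and at most -0.54 on the control arrays, and control array 3 had the lowest touch and jasmonate means of the controls.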

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

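Of the tests in this part, those on handling of the stems, on a younger stage and on the share of epidermis were chosen after the result was seen.

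The number of genes changed was set against other groupings of the same arrays. Only 1 of the 35 splits of the 8 arrays into 4 and 4, the real split, gave as many genes as the 10634 counted. The highest of the other splits gave 0. Every other split mixes the groups, so a large group difference enters its residual spread and keeps its count low. With 35 splits, 1 is also the fewest that can reach the real count, so chance is not excluded by this comparison. The comparison also says nothing about the slides, since the real split is also the split by slide.

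The first pattern is the fall of touch, wound and jasmonate genes in the transgenic stems. A difference between the slides in labelling, hybridisation or scanning was judged by the spike-in probes. The bound, set beforehand, was a shift of 1 log2 unit, and no detected probe reached it. All 8 detected probes did shift, by 0.38 to 0.50, with 0.499 the largest. The mean of the jasmonate list differed by -3.92 and that of the touch and wound list by -3.74. A shift common to all probes was thus smaller than these falls. Slide effects on particular probes, or on the RNA before the spike-in was added, would not show in the spike-in probes and stay open. Handling of the stems at harvest stays open: the 4 control arrays, all of 1 genotype, spanned 4.49 log2 units in the jasmonate mean and 1.15 in the touch and wound mean, but none reached the transgenic range, so handling and genotype cannot be told apart for these genes. The touch and wound mean was at least 3.23 on the control arrays and at most 1.42 on the transgenic arrays, which spanned 2.09, and without control array 3 the jasmonate mean differed by -4.89. An effect of the transgene, which the design names, is also open and was not tested apart from the slide.

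The second pattern is the rise of growth, epidermis and division genes. The largest spike-in shift is the same here, 0.499 log2 units, and again under the bound. After the scaling it cannot size a shift common to all probes of a slide. The differences were 1.95 for the expansin mean, 1.63 for the epidermis mean and 1.22 for the mean of dividing cells. Slide effects on particular probes stay open here as well. A younger stage of the sampled stem stays open. The control arrays spanned 1.47 log2 units in the expansin mean. Control array 2 lay nearest to the transgenic arrays at -0.54, yet it stayed below their lowest value of 0.40. That spread does not measure stage, so stage and genotype cannot be told apart. A larger share of epidermis also stays open: the log2 changes of its genes had a standard deviation 4.08 times their median standard error, but these genes differ in how far they are confined to epidermis and in nearness to the floor, so this spread decides nothing. An effect of the transgene stays open.

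Among 244 sets of 4 values (named genes, list means and array measures, each group apart), 23 had 1 array apart from the others of its group; chance gives about 1 in 20, or 12.2. In 8 of the 23 the other 3 arrays lay at the floor, which fixes the ratio at 1 however small the gap. Without the sets that had 3 or more values at the floor, 15 of 233 remained, against 11.7 by chance. The ratio given is the gap to the nearest array over the group's range. Control array 3 was below the others for AT1G70390 (0.943), GRX480 (0.891), AT4G27654 (0.867), RRTF1 (0.851), WRKY40 (0.885) and LUX (0.841). Control array 2 was above the others for ADS4 (0.848), and it was the only control array above the floor for AT1G62770, AT4G34770, SAUR9 and PME5, as control array 4 was for AT1G62333, transgenic array 2 for AGC2-1 and GRX480, and transgenic array 4 for JAZ7 (a ratio of 1 in each). Transgenic array 1 stood apart for WSD1 (0.942), PSAD1 (0.846), the epidermis mean (0.953) and the auxin response mean (0.899), transgenic array 2 for CYP98A3 (0.862) and CGR3 (0.900), and transgenic array 4 for KNOLLE (0.860) and OPS (0.972).

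Signals outside the comparison were also present. Of 4447 usable probes with no locus in the gene table, 1054 were higher and 860 lower in the transgenic stems. The detected spike-in probes were shifted by a median of 0.44 log2 units.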

How the results depend on the processing

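Spike-in scaling and the fit without control arrays 2 and 3 together were chosen after seeing the data. The slide could not be run as a block, since each slide held 1 group.

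Of 10634 called genes, each judged by its chosen probe, none passed in the opposite direction under any alternative fit except 2 with the mean of a gene's probes. The counts of genes stayed within 1.5 times under the alternatives they were run for, other than these; at the other thresholds only the higher and lower genes were counted, not those with a 2-fold change. The lower genes numbered 2981 with the value table, which keeps each array's brightness, 7600 with every probe on its own, which tests more features, and 3230 at an adjusted p under 0.01. Spike-in scaling gave 2104 higher and 7843 lower genes, 1200 and 3457 of them at least 2-fold, by its shift of all genes. Under it the named gene EF1A reversed to -0.0650, and NST3 read -0.96 and NST1 -0.97, both past the threshold. Camera then placed xyloglucan endotransglucosylases (adjusted p = 7.40e-05) and AP2/ERF relatives (adjusted p = 0.0273) above other genes. The AP2/ERF list holds ERF035, which the construct itself expresses, and had a median of -0.30 here. No test was run without ERF035, so that call cannot be read as one on its relatives. NST3 also passed with normexp (-0.59).

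Replicate numbers did not pair the arrays: the deviations of same-numbered arrays correlated at -0.04, -0.20, 0.16 and -0.40, and 1 of 4 control arrays correlated best with its own number. With the replicate block 4715 genes were higher and 3904 lower, NST3 passed at -0.52, and the xyloglucan synthesis list no longer passed (0.0689). Named genes that lost their call under it were CTL2 (0.0598), CESA4 (0.0516), COBL4 (0.0532), IRX15L (0.0960) and EF1A (0.0608). IRX15L also lost it with normexp (0.0560) and no filter (0.0959), and EF1A with quantile normalization (0.0956), the value table (0.0624) and the mean of probes (0.785).

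Camera with an estimated correlation ended all 17 list calls, and all of its estimates for the lists exceeded the preset value. Heat shock lost its call at an estimate of 0.028, close to the preset 0.01, so the size of the estimate does not account for every lost call. The adjusted p was 0.456 for cambium and heat shock, 0.570 for secondary wall transcription factors, primary wall cellulose, pectin synthesis, pectin modification, expansins, arabinogalactan proteins, cold and dehydration, epidermis, photosynthetic tissue, dividing cells, touch and wound, and jasmonate, 0.602 for xyloglucan synthesis and for vessels, and 0.631 for xylan synthesis. Fry, which does not compare a list with other genes, called 22 lists, among them all 17. Beyond these, fry called secondary wall cellulose (0.0328), xyloglucan endotransglucosylases (0.00543), AP2/ERF relatives (0.0203), salicylate (0.0482) and auxin response (0.0156). Its AP2/ERF call again includes ERF035 itself.

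The list of secondary wall cellulose passed with quantile normalization (0.0463), no filter (0.0378), every probe on its own (0.0453), array weights (0.0360) and without control arrays 2 and 3 (0.0412). The xyloglucan endotransglucosylases passed with normexp (0.0458), median scaling (0.0344), the value table (0.0134), the mean of probes (0.0409), array weights (0.0237) and without control arrays 2 and 3 (0.0109). Salicylate genes passed with every probe on its own (0.00313; median -1.07), where the cold and dehydration median was 0.45. With no filter the medians were 1.19 for pectin modification, 0.50 for expansins and -0.14 for heat shock. Without control arrays 2 and 3 the lists of xyloglucan synthesis (0.0657) and of cold and dehydration (0.0763) did not pass. The cause of these changes was not tested.

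Leaving out 1 array at a time, the adjusted p ran from 0.0209 to 0.0894 for cold and dehydration, 0.00606 to 0.0509 for pectin synthesis, 0.0204 to 0.106 for secondary wall cellulose, 0.0180 to 0.0795 for vessels, 0.0104 to 0.0894 for xylan synthesis, 0.00583 to 0.132 for xyloglucan endotransglucosylases and 0.0180 to 0.139 for xyloglucan synthesis. Each highest value came without control array 3. NST1 ran from -0.71 to -0.36 and NST3 from -0.70 to -0.37. Signal over background limits dim genes: with all 8 arrays required above background, 18176 genes could be tested.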

Other observations

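The families below, their tests and the test of the clock were chosen after seeing the data; the second list of clock genes was written before its values were seen. Genes were grouped by the stem of their symbols into 136 families with at least 10 measured members, and camera at the preset correlation called 11 families higher and 15 lower in the transgenic stems. None passed with an estimated correlation, where the lowest adjusted p was 0.783. SAUR genes, small auxin-induced genes of elongating tissue, formed the family with the largest median rise among those called. Of 14 measured members 13 rose, with a median of 3.92 log2 units (adjusted p = 0.00576), among them SAUR20 at 4.96 ± 1.18 and SAUR19 at 4.85 ± 1.21 (SE, n = 4 per group); members of this family are close copies whose probes can share transcripts. OVATE family proteins, which shape organs, rose in 11 of 13 cases, with a median of 1.60 (adjusted p = 0.00605), led by OFP13 at 2.73 ± 0.37 and OFP12 at 2.72 ± 0.49. Of 30 IQD genes, which encode calmodulin-binding proteins of microtubules, 21 rose and 3 fell (median 0.69; adjusted p = 0.00701). The SAUR median was 3.11 with normexp background correction, 4.52 with the authors' value table and 5.15 without control arrays 2 and 3. With spike-in scaling 12 SAUR, 8 OFP and 11 IQD genes rose, and 6 IQD genes fell.

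Of the families called lower, 4 are given here. Of 24 calcium-dependent protein kinase genes 14 fell and 4 rose, with a median of -0.53 (camera adjusted p = 0.00552), and CPK28 and CPK32 read -3.99 ± 0.33 and -3.01 ± 0.29. Of 11 PERK receptor kinase genes 9 fell and none rose, with a median of -1.37 (adjusted p = 0.00552), or -0.56 with normexp background correction. Of 11 ABCC transporter genes 10 fell and 1 rose, with a median of -0.78 (adjusted p = 0.00552), and ABCC3 read -3.04 ± 0.16. WRKY transcription factors fell in 21 of 46 cases and rose in 8, with a median of -0.53 (adjusted p = 0.0161). WRKY22 and WRKY48 read -5.30 ± 0.61 and -4.67 ± 0.50, while WRKY54 rose by 2.61 ± 0.37. With spike-in scaling 18 CPK, 9 PERK, 10 ABCC and 29 WRKY genes fell, and 12, 8, 6 and 16 with the authors' values. WRKY12, which holds back secondary walls in pith, read -1.26 ± 0.29.

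The third pattern is in the clock genes: in the list fixed beforehand CCA1, LHY, PRR9 and RVE8 were lower in the transgenic stems (-1.24, -1.57, -0.68 and -1.63), and PRR5, LUX and GRP7 were higher (1.39, 1.60 and 1.21). The list also holds PRR7, TOC1, GI, ELF4 and RVE1, and 5 of its 12 genes did not pass, so the pattern rests on part of it. The hypothesis of a later time of harvest was tested on a second list, where 8 evening genes changed by 1.17 log2 units more than 10 morning genes (mean 0.87 against -0.30; exact one-sided permutation test across genes, which are not independent, p = 0.00462). Of the evening genes 6 rose and none fell, led by COR28 at 2.75 ± 0.37, and of the morning genes 5 fell and RVE7 and COL1 rose. Without COR28 and COR27, which also respond to cold, the difference was 0.78 (same exact permutation test, p = 0.0231), a test added after seeing these values; the cold and dehydration list had also risen. The difference in the second list and part of the first list go with a later harvest, and the rest of the first list does not add to it. The labels used here give no time of day, and an effect of the transgene on the clock was not tested, so the cause stays open.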
